A study of Mus musculus with 3 samples.

How the data were processed

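RNA from 3 pools of mouse cells, each of 5 samples per the series' design text, was hybridised to 1 one-colour (Cy3) expression array per pool: MF (spleen fibroblasts with a control lentivirus), iHep (hepatocyte-like cells made with a lentivirus carrying 3 transcription factors) and PH (freshly isolated hepatocytes). Groups were taken from the sample titles. The deposited scanner files hold spot intensity values on a linear scale; per the file headers they were made with Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes name version 9.1. Per the file headers the processed intensity is background-subtracted and detrended within the array, with no normalization between arrays, and the array design was annotated on mm9. The authors' value table holds log2 values for 26049 probes, deposited with scale and centring unstated. Set against the scanner values it correlated at 0.9968, 0.9978 and 0.9903 for MF, iHep and PH, its columns share a highest value of 17.37 and have medians of 7.02, 7.01 and 7.07, and differences between its columns ran the same way as the scanner's with slopes between 0.90 and 0.94; its exact normalization stays unknown. It served as an alternative.

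The values used here were log2 of the processed intensity minus each array's 75th percentile. Control spots and spots marked by the software as non-uniform or population outliers were left out (190, 230 and 383 spots on MF, iHep and PH of 43020 non-control spots each), and no spot was saturated. Replicate spots were averaged, giving 39429 probes. Probes were named by matching the unversioned transcript accession of the design to a RefSeq gene table of assembly GRCm38.p6, used for names alone; because the builds differ no coordinates are given. A total of 27234 probes (69.1%) had 1 symbol, none had several and 12195 had no name here, which left 20577 genes. For the 5476 genes with more than 1 probe, the probe with the highest mean level over the 3 arrays was used. A gene counted as above background on an array when any of its probes was well above background in the software's call; the probe used was not itself the one above background for 40, 57 and 29 of these genes on MF, iHep and PH, and no fold is printed for such a gene. Where a gene was above background on 1 of the 2 arrays compared, the difference is a bound, "at least" N-fold, from the higher of the dim reading and the lowest level of any probe well above background on that array (-6.30, -7.32 and -6.89 for MF, iHep and PH). No fold was formed where neither side was above background.

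With 1 array per group no test, p-value or SD between samples can be given, and the number of arrays limits the precision. Genes were counted at a fixed 2-fold threshold, and at 8-fold. Technical error was estimated from the probes printed 10 times (399 in all) that were above background on an array (301, 314 and 346 on MF, iHep and PH), and disagreement between probes from genes with at least 2 probes; 59, 166 and 159 genes had probes differing by 2-fold in opposite directions for iHep over MF, PH over MF and iHep over PH. Before the data were examined, 47 gene lists with 902 genes were fixed for liver functions, fibroblast states, other cell types and general cell programmes; 872 matched a measured gene. A list is described by its members at least 2-fold higher and lower and its median, taken over measured differences, so that a reading not above background enters as read. The median with such differences held at their bounds is usually smaller in size and is printed beside it where the gap matters. Each median was also set against 10000 random lists matched on mean level in 20 bins. Named genes follow a rule fixed at the same point: a list of anchor genes, the 10 highest and lowest differences and 5 largest bounds per comparison, up to 4 members of each list in its main direction and 2 in the other, and, among genes 8-fold higher in PH, those nearest to PH or MF in iHep and those highest in iHep alone. A gene taken by the rule for 1 comparison is also given in others. Aqp5, Cdh16, Cubn, Foxj1, Gpc4, Lyz1, Muc13, Pax8, Sirpa, Trem2, Try4 and Try5 lie outside the rule and were chosen after their values were seen.

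Alternatives each replaced 1 step of the main setting: normexp background correction (limma 3.58.1 in R 4.3.3, offset 50) on the spots' median signal and background, quantile normalization, scaling to the median of probes above background on all arrays, the authors' processed values, only probes above background on all 3 arrays, no filter on dim probes, the mean of a gene's probes, and thresholds of 4-fold and 1.5-fold. The normexp setting also takes raw median signals in place of detrended processed ones, and the authors' values differ in normalization and in the probes covered, so these alternatives change more than 1 choice. The planned normexp on mean signals was run on median signals. A common background floor for all arrays was chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The steps were tested on simulated data in which 50 genes were changed at each of 4 folds on arrays drawn from the MF profile with real brightness and spot noise. For iHep over MF (16561 genes) the steps recovered 100.0% of genes changed 2.5-fold, 4-fold and 8-fold and called 0 of 16361 unchanged genes; for PH over MF (16015 genes) the same shares were recovered and 0 of 15815 unchanged genes called. Genes changed 1.5-fold were below the threshold and none was called. A list of 20 genes raised in the simulation had medians of 2.02 and 1.86 and stood at percentile 100, and an unchanged one 0.02 and 0.05, at percentiles 72.3 and 87.1. The simulation holds spot noise only, which is far below the 2-fold threshold, so full recovery followed from its settings. The changed genes were drawn from those above background in MF and well clear of its background floor. Recovery of genes near background in MF, such as many liver genes here, was not tested. Other arrays that the series' design names, of spleen and liver tissue, were not analysed here. Certain genes, and the result of 1 short list, are not reported here.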

Results

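Gene expression was measured on 3 one-colour arrays, each hybridised with RNA pooled from 5 samples. MF were primary fibroblasts from mouse spleens remodelled with SiO2 that had received a control lentivirus. iHep were hepatocyte-like cells made from the same kind of fibroblasts with a lentivirus carrying 3 transcription factors, collected 14 days after transduction like MF. PH were freshly isolated primary hepatocytes, included as a positive control. There was 1 array per group, so no difference has a replicate check and no test was possible; "higher" and "lower" below describe these arrays. Levels are log2 signals relative to the array's 75th percentile, which is level 0. That percentile was 544.3 on the MF array, 3751.5 on iHep and 2080.9 on PH, so the MF array was much dimmer. Of 20577 named genes, 15008 were well above background in MF, 16374 in iHep and 17380 in PH. Replicate spots on an array gave a technical SD of a log2 difference between 0.14 and 0.15, whereas different probes of a gene differed with a pooled SD of 0.84 for iHep over MF, 1.11 for PH over MF and 1.09 for iHep over PH. The 2-fold threshold is therefore well outside spot noise but about as large as the disagreement between probes. The iHep and PH arrays shared a scan and MF was scanned apart, so in comparisons with MF the scan and the group cannot be told apart.

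The first comparison asks how cells given the 3-factor virus differed from the control-virus fibroblasts. iHep carried far less of the fibroblast transcript set than MF: 36 of 40 fibroblast genes were at least 2-fold lower and 1 was higher, with a median log2 difference of -3.49. Thy1, a fibroblast surface glycoprotein, was 8163-fold lower, Postn, a secreted matrix protein, 3470-fold lower, and Lox, the collagen cross-linking oxidase, at least 3072-fold lower. The differences were uneven. The collagen genes Col1a1 and Col1a2 were 5.52-fold and 18.3-fold lower, and with levels of 4.62 and 2.45 they still lay far above the 75th percentile in iHep. The intermediate filament Vim was 3.48-fold lower at a level of 4.48, and the growth factor receptor Pdgfrb was 2.53-fold lower at 3.68. Zeb2, a repressor of epithelial genes, was 2.18-fold higher by the brighter of its 2 probes, while the other probe read -0.91 in iHep against 0.16 in MF.

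Contractile genes were lower too. Of 20 myofibroblast and contractile genes 18 were lower and 1 was higher, with a median of -3.06. Acta2, smooth muscle actin, was 682-fold lower and the myosin light chain Myl9 3457-fold lower, while Ankrd1, a stretch-responsive cofactor, was 4.52-fold higher. The hepatic stellate list had 9 of 12 genes lower and none higher, with a median of -2.67 (-1.74 in the authors' values), and the splenic stroma list 7 of 15 lower and 2 higher, with a median of -0.73 (-1.61 under normexp, -0.20 under quantile normalization). Pdpn, the reticular fibroblast marker podoplanin, was at least 4174-fold lower.

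Several regulators of the liver programme were higher in iHep, but the class median lay within the range of matched random lists, -0.75 to 0.83. Hnf4a, a master nuclear receptor of hepatocytes, was 101-fold higher, Foxa2 30.5-fold higher and the bile acid receptor Nr1h4 15.0-fold higher. Cebpa, a driver of hepatocyte maturation, was 18.4-fold lower. Of 20 liver-enriched transcription factors 9 were at least 2-fold higher and 1 was lower, with a median of 0.67 that was 0.51 with bounds and -0.42 under normexp background correction. Gata4, a regulator of early liver development, was 4.10-fold higher, and the forkhead factor Foxa3 was at a level of -5.99 in iHep and not well above background in MF. The labels do not name the 3 factors, and whether any probe read a viral copy was not tested.

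Secreted liver products read low on both arrays, with a median level of the plasma protein list of -5.20 in MF and -4.60 in iHep, although 27 and 39 of its 41 genes were well above background. Among 39 plasma protein genes, 14 were at least 2-fold higher in iHep, 5 were lower and 20 lay within 2-fold, with a median of 0.96 (0.45 with differences held at their bounds, which 12 genes need), which turned to -1.23 under normexp (5 higher, 11 lower). Rbp4, the retinol carrier, was 32.1-fold higher and Cp, ceruloplasmin, 17.2-fold higher, both at levels above 2. Albumin (Alb) stood at -4.75 in iHep and -5.20 in MF, transthyretin (Ttr) at -5.72 in iHep, and Apoa1 was not well above background in either. Apoe, abundant in MF, was 45.5-fold lower. Afp, the fetal counterpart of albumin, was 20.1-fold higher; of the 10 fetal liver and progenitor genes compared, 6 were higher and 2 lower, with a median of 2.52 that was 1.82 with bounds and -0.39 under normexp. The oncofetal regulator Hmga2 was 8.43-fold higher, while the glypican Gpc3 was 13.2-fold lower.

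Cyp3a11, a major drug-metabolising cytochrome P450, was at least 32.6-fold higher, and Cyp1a1 at least 23.8-fold higher, but Cyp1b1, a P450 of mesenchymal cells, was 1443-fold lower, and the list had 10 of 31 genes higher and 4 lower. The amino acid catabolism list had 8 of 31 genes higher and 7 lower, with Cth 19.7-fold and Gldc 15.7-fold higher. Bile acid synthesis and transport had 4 of 16 higher and 3 lower, glucose and glycogen metabolism 4 of 18 higher and 2 lower, coagulation and complement 7 of 24 higher and 5 lower, and major urinary proteins 3 of 7 higher and none lower. The medians of these 6 lists, which were 0.99, 0.91, 0.94, 0.51, 0.48 and 1.42, all turned negative under normexp, at -1.51, -1.17, -1.46, -0.22, -0.99 and -0.89. With differences held at their bounds they were 0.35, 0.54, 0.38, 0.28, 0.13 and 0.96. Conjugating enzymes (6 of 30 higher, 10 lower), fatty acid oxidation and ketogenesis (3 of 23 higher, 4 lower) and the urea cycle (2 of 11 higher, 2 lower) had medians of -0.02, -0.02 and 0.07, which were -1.21, -0.37 and -0.89 under normexp; that of conjugating enzymes was 0.03 under quantile normalization. Arg1, Otc and Pck1, which hepatocytes use for urea and glucose production, were not well above background on either array. Lipogenesis and lipoprotein genes had 8 of 24 higher and 2 lower, with a median of 0.76, which was 0.57 with bounds and 0.15 under normexp. Cholesterol synthesis (2 of 22 higher, 7 lower) and iron and heme (3 of 18 higher, 8 lower) had medians of -0.48 and -0.83, which were -0.15 and -0.66 under quantile normalization.

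Epithelial structure was a clearer difference. Of 25 epithelial genes 14 were at least 2-fold higher in iHep and 4 lower, with a median of 1.81, which was 0.56 under normexp. The keratins Krt8 and Krt18 were 33.2-fold and 19.9-fold higher, and Cdh1, E-cadherin, at least 36.4-fold higher, whereas the tight junction gene Cldn3 was at least 10.9-fold lower. The desmosomal protein Dsp was 34.4-fold higher by the brighter of its 2 probes, while the other was not well above background in MF or iHep. The cholangiocyte list had 6 of 13 genes higher, among them the water channel Aqp1 at 34.1-fold and Krt19 at 5.14-fold, and 2 lower; its median of 1.31 was 0.52 with bounds and -0.20 under normexp.

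Proliferation genes were higher together: 27 of 30 cell cycle genes were at least 2-fold higher in iHep and none was lower, with a median of 2.01. Aurka and Bub1, which act in mitosis, were 8.57-fold and 7.85-fold higher, Mki67 3.38-fold and Myc 5.11-fold. The senescence and p53 list stood the other way, with 10 of 18 lower, 3 higher and a median of -1.47. The cell cycle inhibitors Cdkn2a and Cdkn2b were 16.7-fold and 5.95-fold lower, and Igfbp5 74.7-fold lower, while the stress gene Sesn2 was 4.62-fold higher. Among inflammation and acute phase genes 9 of 21 were higher and 2 lower, with the chemokines Cxcl1 at 33.3-fold and Cxcl2 at least 127-fold; the median of 1.09 was 0.62 with bounds and -0.30 under normexp. Interferon-stimulated genes had 8 of 24 higher, such as Oas2 at 14.5-fold, and 2 lower, such as Ifit3 at 9.13-fold, with a median of 0.17 (0.41 under quantile normalization).

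Macrophage genes, like fibroblast genes, were lower. MF carried them at high levels, with C1qc at 4.81 and Ctss at 4.69, and 17 of 20 macrophage genes were at least 2-fold lower in iHep and 1 was higher, with a median of -5.91. C1qc, a complement component made by macrophages, was at least 4503-fold lower and the lysosomal protease Ctss 1975-fold lower. The Kupffer and red pulp macrophage list had 7 of 10 lower and 2 higher, with a median of -3.51, and the endothelial list 8 of 16 lower and 3 higher, with a median of -1.35 (-0.90 with bounds, -2.26 under normexp, -0.69 under quantile normalization). Xist, the RNA of the inactive X chromosome, was at -2.44 in MF and not well above background in iHep, at least 29.6-fold lower.

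Set against random lists of matched level, the medians of the fibroblast, myofibroblast and macrophage lists in iHep over MF stood at percentile 0.00. The endothelial list stood at 0.42 (1.96 with bounds), the plasma protein list at 99.8 (98.6 with bounds, although its median was -1.23 under normexp), and the epithelial and cell cycle lists at 100. Among other liver lists, lipogenesis and lipoprotein stood at 99.1, amino acid catabolism at 98.7 and cytochrome P450 enzymes at 98.3. With bounds these were 98.6, 99.1 and 95.1. The P450 median with bounds, 0.35, then lay inside the range of random lists, -0.44 to 0.44. Liver-enriched transcription factors stood at 93.9, bile acid synthesis and transport at 91.4, coagulation and complement at 85.1 and glucose and glycogen metabolism at 81.2. The urea cycle stood at 50.1 and conjugating enzymes at 36.0. The cholangiocyte and inflammation lists stood at 99.6 and 99.9, or 95.4 and 98.65 with bounds. The cholangiocyte median with bounds, 0.52, lay inside its range of -0.91 to 0.63. In PH over MF the macrophage list stood at 35.2 and the fibroblast list of iHep over PH at 96.1.

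Across the 17176 genes above background on at least 1 of these arrays, 3409 were at least 2-fold higher in iHep than MF and 4043 lower, and at 8-fold 462 were higher and 1183 lower. Higher genes made up 45.7% of those differing, against 27.4% under normexp, 50.9% under quantile normalization and 49.8% in the authors' processed values. These moved the median of all compared genes by -0.73, 0.12 and 0.09. The 10 genes with the greatest difference among those above background on both arrays included Pnma5 (157-fold), H2-M10.1 (120-fold), Ugt2b34 (104-fold) and Gcnt3 (104-fold). At the other end stood Gas6, 7523-fold lower, the small heat shock protein Hspb1, 4248-fold lower, and, as bounds, Gpx3, Timp3, Meg3 and Ckap4, each at least 4356-fold lower. A fold is given as "at least" where the gene was not well above background on the dimmer side; it sets the brighter level against the higher of that gene's own reading and the lowest level of any probe well above background on that array.

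**Figure D1:**
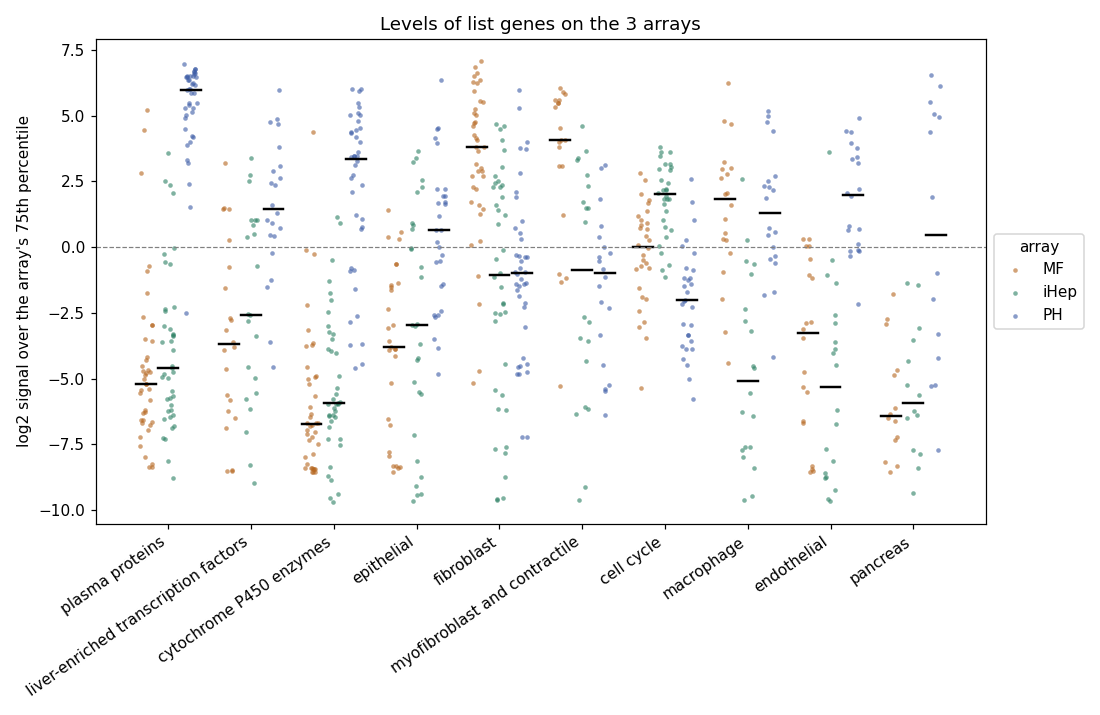
Levels of the genes of 10 lists on the MF, iHep and PH arrays, as log2 signal over each array's 75th percentile (dashed line). Each point is a gene, measured on 1 array, and black bars are medians. The median difference of iHep from MF was -3.49 for fibroblast genes, 2.01 for cell cycle genes and -5.91 for macrophage genes; plasma protein genes stood far higher in PH, with a median difference of 10.55 from MF.

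The second comparison sets the positive control against the same fibroblasts and gives the size of the hepatocyte signal on these arrays. All 41 plasma protein genes were at least 2-fold higher in PH, with a median log2 difference of 10.55. Alb was 3754-fold higher, Ttr at least 7048-fold and Apoa1 at least 1770-fold. Hnf4a was 3133-fold higher, and 20 of 22 liver-enriched transcription factors were higher with a median of 4.77. Fibroblast genes were lower in 36 of 40 cases and higher in 3, with a median of -4.56, and myofibroblast and contractile genes in 18 of 20, with a median of -5.28. Acta2 was 99.8-fold lower, Thy1 69.7-fold lower and Itga11 906-fold lower.

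Cytochrome P450 enzymes had 38 of 40 genes higher, with Cyp2e1 1987-fold and Cyp3a11 at least 2690-fold higher, and Cyp1b1 lower at 63.7-fold; the median was 9.62. Amino acid catabolism (35 of 35 higher, median 7.68), bile acid synthesis and transport (20 of 21, 8.62), conjugating enzymes (36 of 39, 6.85), urea cycle and ammonia (13 of 13, 5.05) and glucose and glycogen metabolism (20 of 21, 6.47) all stood higher, as did coagulation and complement (28 of 31, 8.70) and major urinary proteins (7 of 7, 11.59). Arg1 was at least 2691-fold and Pck1 at least 4616-fold higher. Both zones of the lobule were represented, with 16 of 17 pericentral genes (median 6.99) and 15 of 16 periportal genes (7.67) higher. Male-biased liver genes were higher in 22 of 22 cases, with a median of 9.47, and female-biased ones in 10 of 13, with a median of 3.37 that was 2.06 with bounds and -0.12 under normexp. Fatty acid oxidation and ketogenesis had 21 of 24 higher (median 2.44), lipogenesis and lipoprotein 19 of 25 (2.78), iron and heme 10 of 19 (1.82), cholesterol synthesis 8 of 22 (0.63) and oxidative phosphorylation 6 of 21 (0.65). Epithelial genes were higher in 26 of 29 cases, with a median of 4.64. With bounds the medians were 7.75 for bile acid synthesis and transport, 5.89 for glucose and glycogen, 6.70 for periportal, 8.39 for male-biased and 3.87 for epithelial genes. Under normexp several of these medians were much smaller, at 5.10 for bile acid synthesis and transport, 6.42 for cytochrome P450 enzymes, 6.04 for male-biased liver genes, 3.13 for liver-enriched transcription factors and 2.06 for epithelial genes; in the authors' values the glucose and glycogen list stood at 4.07 and lipogenesis and lipoprotein at 1.23, oxidative phosphorylation at 0.41, and cholesterol synthesis had 4 of 15 genes higher and 4 lower.

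Cell cycle genes were lower in PH in 24 of 30 cases and higher in 2, with a median of -2.08, and senescence and p53 genes lower in 12 of 18, with a median of -2.03. Cdkn2a was 847-fold lower. Glycolysis genes were lower in 11 of 17 cases and higher in none (median -1.86; Pkm 14.8-fold lower), and ribosomal proteins lower in 11 of 22 (median -0.99). Inflammation and acute phase genes had 14 of 24 higher and 5 lower, with a median of 3.83 (2.19 under normexp); the acute phase gene Saa2 was at least 5679-fold higher, whereas the chemokine Ccl7 was 544-fold lower. The fetal liver and progenitor list had 4 of 9 genes higher and 3 lower, with a median above 0 that was -0.58 under normexp and -2.38 in the authors' values, and the hepatic stellate list 7 of 15 higher and 6 lower, with a median of 0.10 that was -0.62 under normexp. The immediate early and isolation stress list had 7 of 17 higher and 7 lower, with Zfp36 29.7-fold and Fos 3.27-fold higher.

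Genes of other cell types stood beside the hepatocyte genes on the PH array. Pnlip, pancreatic lipase, was at least 7436-fold higher in PH than MF, the protease Ctrb1 532-fold and Cpa1 at least 3657-fold, at levels of 6.56, 6.14 and 5.53. Of 13 pancreas genes 12 were higher in PH than MF, with a median of 6.33, or 4.32 with bounds, which 7 genes need. Endothelial genes were higher in 18 of 20 cases, with a median of 5.61 (4.74 with bounds); Stab2 of the liver sinusoid was 157-fold higher and Cdh5 at least 722-fold. The Kupffer and red pulp macrophage list was higher in 8 of 12 (median 2.63; Clec4f at least 636-fold), the T and NK lymphocyte list in 13 of 16 (4.17), B lymphocyte in 10 of 12 (2.85), neutrophil in 9 of 11 (4.42, or 3.23 with bounds) and erythroid in 7 of 8 (4.34), the last although the labels' protocol includes a globin removal step. Normexp gave smaller medians here too, at 3.48 for pancreas, 1.01 for neutrophil, 1.31 for B lymphocyte, 2.20 for T and NK lymphocyte and 1.76 for Kupffer and red pulp macrophage. General macrophage genes were about as high in PH as in MF, with a median of -0.36. The Y-linked genes Ddx3y and Eif2s3y had levels of -0.26 and 1.64 in PH and were not well above background in MF or iHep. Xist was not well above background in PH. In iHep 0 of the 5 genes of the Y-linked and Xist list were well above background, so they mark neither sex there. The labels give female for all 3 samples, which the Y-linked readings of PH go against. Differences of the male-biased and female-biased lists between PH and the other arrays therefore cannot be told apart from a difference in sex. Across the 17787 genes compared, 5488 were at least 2-fold higher in PH than MF and 4515 lower, so that 54.9% of differing genes were higher, against 38.7% under normexp, 43.0% under quantile normalization and 42.1% in the authors' processed values; these moved the median of all compared genes by -0.63, -0.32 and -0.31.

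**Figure D2:**
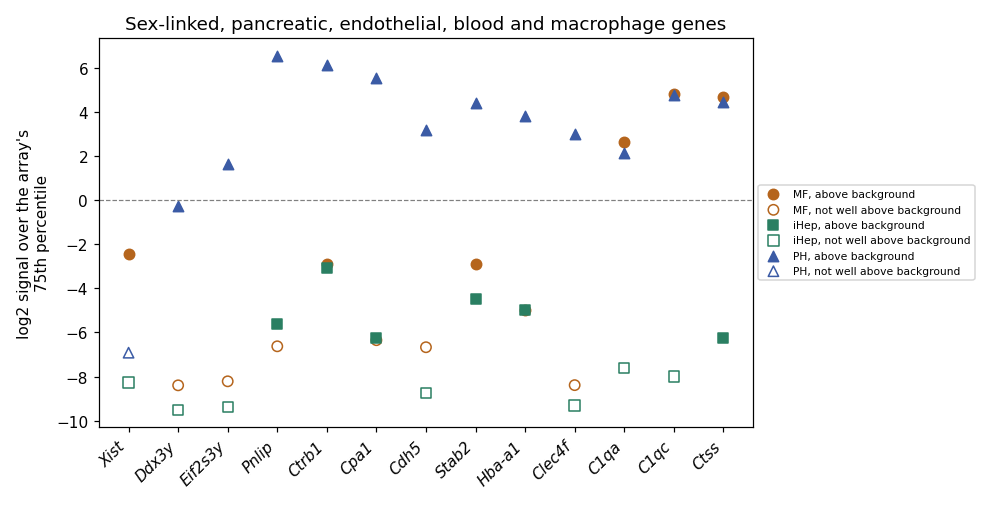
Levels of sex-linked, pancreatic, endothelial, blood and macrophage genes on the 3 arrays, as log2 signal over the array's 75th percentile (dashed line). Each symbol is 1 gene on 1 array and open symbols are not well above background. Pnlip (6.56), Ctrb1 (6.14) and Cpa1 (5.53) were high only on the PH array, while C1qc was high on MF (4.81) and PH (4.76) and not well above background on iHep.

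The third comparison, within 1 scan, asks how near iHep came to the positive control. The plasma protein genes were at least 2-fold lower in iHep in 41 of 41 cases, with a median log2 difference of -9.91. Alb was 2743-fold lower and Ttr 4707-fold, and Serpina3k, a serine protease inhibitor of the liver, had a log2 difference of -13.35. Hnf4a, in spite of its high level, was 31.0-fold lower than in PH, Gata4 6.25-fold and Foxa3 120-fold, and 18 of 22 liver-enriched transcription factors were lower, with a median of -3.29. Foxa2, at 1.01 in iHep and 1.29 in PH, was an exception. Cyp3a11 was 82.6-fold lower and Cyp2e1 1001-fold, and 37 of 40 cytochrome P450 genes were lower with a median of -8.13.

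Other liver functions followed. Medians were -8.56 for coagulation and complement (30 of 31 lower), -7.11 for bile acid synthesis and transport (20 of 21), -7.82 for conjugating enzymes (35 of 39), -8.52 for amino acid catabolism (32 of 35), -6.38 for glucose and glycogen metabolism (19 of 21), -4.90 for the urea cycle (13 of 13) and -9.87 for major urinary proteins (7 of 7). Pericentral (16 of 17 lower, -7.96, or -7.11 with bounds), periportal (16 of 16, -7.03), male-biased (22 of 22, -9.46) and female-biased genes (9 of 13, -3.22, or -2.72 with bounds and -1.89 under normexp) were lower too. Fatty acid oxidation and ketogenesis (20 of 24 lower), lipogenesis and lipoprotein (16 of 25), iron and heme (15 of 19) and cholesterol synthesis (12 of 22) had medians of -2.60, -2.37, -1.41 and -1.26; in the authors' values lipogenesis and lipoprotein stood at -0.40, with 6 of 17 genes lower and 3 higher, and cholesterol synthesis at -0.74. Slc10a1, the bile salt importer, could not be placed, since its brighter probe read 4.79 in iHep, 5.62 in PH and 5.99 in MF and its other probe was above background in PH alone.

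Several epithelial genes stood near hepatocyte levels in iHep. Krt18 read 3.66 against 3.98 in PH, Krt8 0.91 against 0.64 and the brighter probe of Dsp -0.06 against 0.67. The other Dsp probe read -4.36 in PH and was not well above background in iHep. Of 29 epithelial genes 18 were lower, and the list median was -2.39. Afp was 23.1-fold higher in iHep than in PH, Hmga2 116-fold and Igf2bp3 110-fold, and the fetal liver and progenitor list had 7 of 10 genes higher and 2 lower, with a median of 1.96, which was 0.72 under normexp (4 higher, 2 lower) and 3.68 in the authors' values. Cell cycle genes were higher in 29 of 30 cases, with a median of 4.24. Fibroblast genes differed in both directions, 15 higher and 15 lower of 39, with a median of 0.34 (0.77 in the authors' values); Pdgfrb was 16.0-fold higher in iHep, whereas Dcn was 590-fold lower. Endothelial (18 of 20 lower, median -8.02, or -7.32 with bounds), pancreas (13 of 13, -6.41, or -5.34 with bounds and -3.66 under normexp), macrophage (18 of 20, -7.06, or -6.16 with bounds) and lymphocyte genes were lower in iHep, with 10 of 12 for the B lymphocyte list and 15 of 16 for the T and NK lymphocyte list. In all, 4183 genes were at least 2-fold higher in iHep than PH and 6479 lower of 18005 compared; higher genes made up 39.2% of those differing, and 55.7% under both quantile normalization and the authors' processed values. The median of all compared genes, -0.30 in the main scaling, was 0.24 under quantile normalization and 0.21 in the authors' values, shifts of 0.54 and 0.51 against which smaller list differences such as those of the fibroblast list should be read.

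To place iHep between the other arrays, genes that separated PH from MF were followed. Of 1922 genes at least 8-fold higher in PH than MF, 628 (32.7%) were at least 2-fold higher in iHep than MF, among them Hnf4a, Cyp3a11 and Krt18, and 223 were at least 2-fold lower. Counted among those above background in iHep or MF the share was 37.3%, against 23.5% among other genes of matched MF level. Only 86 lay within 2-fold of PH. The genes nearest to or above the PH level included Lamb3, Wfdc2, Ano1 and Ppargc1a, which were 8.53-fold, 8.06-fold, 3.75-fold and 3.62-fold higher in iHep than in PH. Of 974 genes at least 8-fold lower in PH than MF, such as Acta2, Thy1 and Itga11, 690 (70.8%) were also at least 2-fold lower in iHep, against 25% among other genes of matched level.

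Across 18204 genes, which are not independent replicates, the differences iHep minus MF and PH minus MF correlated with a Pearson's r of 0.36 and a covariance of 2.13. Both share the MF array. Unchanged groups simulated against it gave r = 0.48 with a covariance of 0.01 from spot noise. From the noise between probes they gave r = 0.49 with a covariance of 0.35. Such an r follows by construction from noise of similar size on a shared array, so the observed r is not to be read as below it. The probe SD of iHep over MF stood for all groups, and the dimness and separate scan of MF were not modelled. Of 16759 genes compared in both, 1536 were higher in both iHep and PH and 2080 lower in both, where independent lists of these sizes would share 975.5 and 1089.2. The MF array cannot be split, so part of that excess may come from the shared control.

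**Figure D3:**
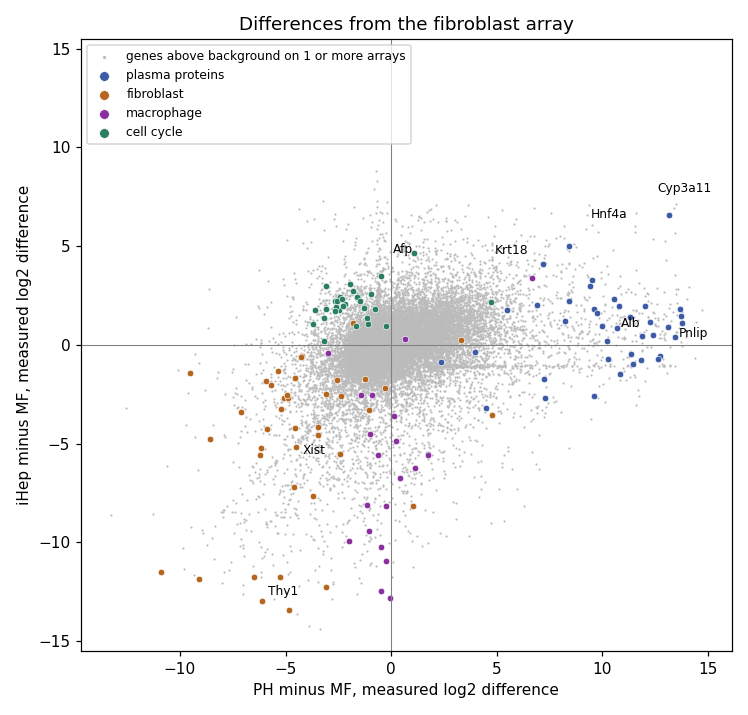
Measured log2 difference of iHep from MF (vertical axis) against that of PH from MF (horizontal axis), for genes above background on at least 1 array, with 4 gene lists coloured. Each point is a gene. Fibroblast genes were lower on both axes, with medians of -3.49 and -4.56, and cell cycle genes were higher in iHep (2.01) and lower in PH (-2.08). Macrophage genes had a median of -5.91 in iHep and of -0.36 in PH, where 5 of 20 were at least 2-fold lower and 3 higher.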

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

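Of the tests in this part, the comparison of pancreatic with unrelated tissue genes and the further leukocyte list were set out before their values were seen. Pancreatic genes of the fixed lists, 8 of which the acinar list holds, had by then been seen high on PH. The high side of that comparison was therefore known. The other tests were chosen only after the results were seen.

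Outside the named genes, 102 probes without a gene name here read at least 8-fold higher in iHep than in both MF and PH. Of 12195 unnamed probes 12105 had a reading left on all 3 arrays; of these 8234 were above background in iHep and 224 were at least 8-fold higher in iHep than MF; the highest exceeded the other arrays by 7.39 on the log2 scale. No explanation was tested for them.

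Pancreatic and endothelial genes read far higher on the PH array than on the MF and iHep arrays; levels of different probes do not give relative transcript amounts. Cross-hybridisation that grows with array brightness is argued against. The same 27 acinar genes were all lower on iHep than on PH, with a median log2 difference of -9.90. The iHep array was brighter at the 75th percentile (3751.5 against 2080.9) and close to PH in median signal (255.8 against 256.1). Its highest signal was lower (206998 against 293163), as was its share of probes above background (75.4% against 79.4%). The acinar median on PH also lay 9.60 above the highest median of neuron, testis germ cell, skeletal muscle and skin keratinocyte genes, a gap between different probes. Cross-hybridisation to hepatocyte RNA was not tested. RNA of pancreas in the PH pool stays open as a hypothesis: 96.3% of the acinar genes lay above the array's 75th percentile (Pnlip 6.56, Try5 6.35, Ctrb1 6.14, Try4 5.81), as did 19 of 19 outside the lists fixed earlier, which hold 8, but this was chosen after pancreatic genes had been seen high on PH. Whether liver tissue stood in place of isolated hepatocytes, or an isolate kept other liver cells, cannot be told apart, because 61.8% of 55 endothelial, macrophage and stellate genes above the percentile would follow from either. No explanation by a change within hepatocytes was tested, and the labels name no step that separates hepatocytes from other liver cells.

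Macrophage genes were high in MF and low in iHep, with median levels of 1.81 and -5.09, although 15 of 20 were still well above background in iHep. The median of -5.91 lies far below the range of -0.77 to 0.73 that matched random lists gave. Dimness and separate scan of the MF array, acting alike on genes of matched level, would not give such a gap. The list was flagged for this same median, so the comparison is not an independent test. Leukocytes in the MF pool that were much rarer in the iHep pool may account for it. Of 27 further leukocyte and macrophage genes above background in MF, 16 (59.3%) were at least 8-fold lower in iHep. That lies between the shares set beforehand for and against. Of the 28 compared in iHep and MF, 25 were at least 2-fold lower and 2 higher, with a median log2 difference of -4.31. A change within the cells could lower these genes too, so no such share could tell it apart from rarer leukocytes. The brightest genes in MF were Lyz1 (6.24), C1qc (4.81) and Ctss (4.69) in the macrophage list and Trem2 (4.55) in the further list. An effect of the 3 factors on the cells themselves stays open as untested.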

How the results depend on the processing

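Comparing main results with each alternative, 103 stayed within their bounds and 21 moved; among other list medians 921 stayed, 138 moved and 18 that were at least 1 in size changed sign. Counting medians of any size, 28 of 141 had the opposite sign under normexp, 8 under quantile normalization, 9 in the authors' values and 1 under median scaling. Of named-gene values 2148 stayed and 201 moved, 121 of them under normexp, where 194 stayed. None changed sign from a main value of at least 1, but a difference held at its bound cannot change sign unless the filter is dropped. Differences and list medians counted as stayed when they shifted by less than the pooled SD between probes, 0.84 to 1.11. A median smaller than that could therefore change sign and still count as stayed. The floor common to all arrays was chosen after the data were seen; the scan as a block was not run, with 1 array per group. With normexp the correlation of iHep minus MF with PH minus MF was 0.24, genes higher in PH than MF numbered 3184 and in iHep than MF 2002, plasma protein medians were 8.29 (PH over MF) and -1.23 (iHep over MF), and the share of PH genes higher in iHep was 23.4%; PH over MF medians turned to -0.021 (cholangiocyte), -0.12 (female-biased liver), -0.58 (fetal liver), -0.61 (heart), -0.57 (intestine) and -0.13 (splenic stroma), and iHep over MF to -0.20 (cholangiocyte), -0.39 (fetal liver), -0.30 (inflammation), -1.39 (intestine) and -0.89 (major urinary proteins). By construction its offset of 50 is a larger part of the dim MF signals (75th percentile 544.3) than of iHep's (3751.5), so low signals on MF are raised most, and signal over background limits what genes near background can tell. With only probes above background on all 3 arrays, 3611 genes were higher in PH than MF and 3996 lower in iHep than PH, fetal liver in PH over MF was -1.99 and the share 41.4%. With no filter the share was 43.9%. Quantile normalization gave a share of 35.6%, fetal liver in PH over MF of -0.026, and in iHep over PH 0.060 (cholangiocyte) and 0.11 (intestine). The authors' values gave 2984 genes higher in PH than MF, 2620 lower in iHep than MF and 3216 lower in iHep than PH, with fetal liver in PH over MF at -2.38 and, in iHep over PH, cholangiocyte at 0.50 and intestine at 0.36; the cause was not tested. A 4-fold threshold gave 3277 higher and 1997 lower in PH than MF, 1200 higher and 1992 lower in iHep than MF, and 1808 higher and 3853 lower in iHep than PH; 1.5-fold gave 5121 higher in iHep than MF.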

Other observations

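The count of genes missing from iHep alone and the tests on kidney, gut and lung lists were chosen only after the result was seen; the counts and medians of the other lists were planned. Some genes were high in iHep and low in both other arrays. Pnma5, a paraneoplastic antigen gene, read 3.80 in iHep, -3.50 in MF and -6.71 in PH. The growth factor genes Areg and Wnt10a were 86.4-fold and 75.8-fold higher in iHep than MF and 219-fold and 99.5-fold higher than PH. Vil1 and Krt20, structural genes of gut epithelium, had differences from MF of at least 6.63 and of 3.32 on the log2 scale, and Tnnt2, cardiac troponin T, was 38.6-fold higher. Of the fixed intestine list 5 of 12 genes were higher in iHep than MF and 2 lower, and 4 of 15 were higher than PH and 8 lower; of the heart list 3 of 15 were higher than MF and 8 lower, and 1 of 16 was higher than PH and 9 lower. In PH over MF the same lists had 7 of 13 and 7 of 16 genes higher, with medians of 2.14 and 1.02 that were 1.35 and 0.77 with differences held at their bounds and -0.57 and -0.61 under normexp.

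Another group read high in MF and PH and not in iHep. In all, 36 genes lay above the 75th percentile of both MF and PH and were not well above background in iHep, against 5 for PH and 0 for MF in the corresponding counts. Beside macrophage genes such as C1qc they included the endoplasmic reticulum protein Ckap4 (4.76 in MF, 1.38 in PH), the protease inhibitor Timp3 (5.19 and 0.22), the surface proteins Pdpn (4.70 and 0.81) and Gpc4 (2.17 and 1.19), and Sirpa (3.82 and 2.22). Ckap4, Timp3 and Gpc4 have 1 probe each, so a failed probe is excluded only as far as the other arrays read it.

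One hypothesis is that the genes high in iHep alone mark a programme of another epithelium. Of the 462 genes at least 8-fold higher in iHep than MF, 67.3% were also at least 2-fold higher than PH, but both comparisons share the iHep array and the genes were picked for a high reading on it, so the dimness and separate scan of MF cannot be told apart from a difference between the cells. Of 24 kidney tubule genes above background on any array 6 (25%) were at least 2-fold higher in iHep than both other arrays, among them Pax8, Cdh16 and Cubn, against 9.4% of all genes. The shares were 21.7% for stomach and gut epithelium (Gcnt3, Krt20, Muc13, Tspan8 and Vil1) and 17.6% for lung and airway epithelium (Aqp5, Foxj1 and Wfdc2). The gut list shares 5 genes with lists fixed earlier, and values of some members had been seen before it was drawn up, so its share is partly counted on genes that prompted the hypothesis; outside the fixed lists 3 of 19 were higher. The lung list shares 2. Taking genes as independent, the 95% intervals of the kidney, gut and lung shares were 12% to 44.9%, 9.7% to 41.9% and 6.2% to 41.0%. The tests asked for most of a list to be higher if a programme was present, and for under 25% if not. The intervals all end below the first of these, so most of the listed genes were not higher in iHep than both other arrays. That cannot decide on a programme, because a gene also had to exceed PH, which itself often read higher than MF. In PH over MF, 13 of 24 kidney, 19 of 23 gut and 13 of 17 lung genes were at least 2-fold higher, with 5, 1 and 1 lower. In iHep over MF, 11 of 22 kidney, 8 of 18 gut and 8 of 16 lung genes were higher, with 3, 0 and 1 lower. The gut and lung shares lie under 25%, but their intervals reach above it. Programmes of these epithelia stay open.

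Other lists gave the following values. Lymphocyte lists in iHep over MF had 1 of 9 (B) and 4 of 11 (T and NK) genes higher and 2 lower in each, with medians of 0.25 and 0.89 that were -1.47 and -1.05 under normexp. The neutrophil list had a median of -1.25, the erythroid list 0.91 (-0.76 under normexp), the pancreas list 0.48 (-1.05), male-biased liver 0.20 (0.00 with bounds, -1.55), female-biased liver -0.30 (-1.38, and -1.13 in the authors' values), pericentral -0.13 (-1.46, 0.09 under quantile normalization and 1.04 in the authors' values) and periportal -0.03 (-1.67, and -1.71 in the authors' values). Glycolysis and ribosomal proteins had medians of -0.87 and -0.99 in iHep over MF, which were -0.07 and 0.05 under quantile normalization, the second also 0.01 in the authors' values. Oxidative phosphorylation, ER stress and immediate early genes lay at 0.03, 0.12 and -0.03. The anchor genes had 9 of 27 higher and 8 lower in iHep over MF, 20 of 30 higher and 7 lower in PH over MF, and 3 of 30 higher and 22 lower in iHep over PH. Of the Y-linked and Xist list 3 of 5 genes were higher in PH than MF and 1 lower, and 4 of 4 lower in iHep than PH. In PH over MF the interferon-stimulated list had a median of 0.04 (-0.20 under normexp) and ER stress -0.05. In iHep over PH medians were -5.59 for Kupffer and red pulp macrophage, -4.90 for neutrophil (-3.33 with bounds, -2.70 under normexp), -3.83 for erythroid, -4.16 for hepatic stellate (-3.40 with bounds, -1.61 in the authors' values), -2.31 for splenic stroma, -1.53 for immediate early and isolation stress, 0.98 for senescence and p53, 0.84 for interferon-stimulated, 0.10 for ER stress (0.68 under quantile normalization, 1.21 in the authors' values) and 0.11 for glycolysis (1.08 and 1.04). There the median of oxidative phosphorylation was -0.74 (-0.11 under quantile normalization), of inflammation and acute phase -0.75 (0.75 in the authors' values), of myofibroblast and contractile 0.08 (-0.09) and of ribosomal proteins 0.01 (-0.10 under normexp, 1.07 under quantile normalization and 0.54 in the authors' values).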
